A study of Mus musculus with 6 samples.

How the data were processed

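Bulk RNA sequencing was performed on ovaries of mice aged 3 months and taken at estrus, with 3 wild-type and 3 Rnf111+/- libraries. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were built with a VAHTS Universal V6 kit. The authors deposited 1 table of whole-number read counts per gene, with a column for each library and gene symbols as identifiers. The submitters' processing notes name fastp (version 0.20.1), HISAT2 (2.1.0), HTSeq (0.11.2) and DESeq2 (1.38.3) and the mouse genome build GRCm39. The role and order of these tools, the gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes, and of close copies such as Mug1 and Mug2, cannot be assumed to be separated. The reference annotation at hand was of the earlier build GRCm38, so it was used for gene names only and no coordinates are given. Of the symbols in the count table, 96.1% were found in it. Every row of the table named a gene, and 0 columns lacked a sample.

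Groups were taken from the genotype given in the labels. Library totals ranged from 38261449 to 39474515 counts, and the genes tested held 99.92 to 99.95% of them. Differences in depth were therefore small, and scaling factors from the trimmed mean of M values (TMM) ranged from 0.98 to 1.018. The detection floor of 3 counts corresponded to 0.0747 to 0.0784 CPM, and such floors and counting intervals cover counting error only, because the sources used here name no molecular identifiers. Counting intervals of ratios of summed counts are exact binomial (Clopper-Pearson) intervals at 95%. Replicates were checked for duplicates by a chi-square test of their counts over genes: the closest pair, wild-type replicates 1 and 2, had a chi-square of 12.4 per degree of freedom, so all 6 were counted as separate.

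Counts as deposited were analysed with edgeR (4.0.16) in R (4.3.3). Genes with low counts were removed with filterByExpr at its defaults (minimum count 10, minimum total 15), libraries were scaled by TMM, and a robust quasi-likelihood model with genotype as its only term was fitted to all 6 libraries. The two-sided quasi-likelihood test was adjusted by Benjamini-Hochberg over all 16841 tested genes, and genes with an adjusted p under 0.05 were called, with no minimum fold. Every adjusted p of a gene comes from this test unless another tool is named. Log2 fold changes are heterozygous over wild type. The test gives no standard error, so it was computed as the absolute log2 fold change divided by the square root of the test's F statistic. Levels are CPM with TMM scaling, as mean ± SD of 3 libraries. Rnf111 was also tested by an exact two-sided permutation of log2 CPM.

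Before the data were examined, 35 gene lists were fixed, with 807 genes, of which 801 were in the count table. They cover SMAD feedback genes and Arkadia substrates, TGF-beta, BMP and activin ligands, receptors and SMADs, TGF-beta and SMAD3 targets, BMP and SMAD1/5 targets, oocyte, granulosa, ovulation and cumulus expansion, corpus luteum, theca and interstitium, cholesterol synthesis, stroma and matrix, smooth muscle and pericyte, endothelium, macrophage and myeloid, lymphocyte, interferon response, inflammatory cytokines and chemokines, ovarian surface epithelium, oviduct epithelium, adipocyte, erythrocyte, cell cycle, DNA repair and meiotic recombination, premature ovarian insufficiency, p53 and apoptosis, senescence, primordial follicle activation and PI3K-FOXO3, immediate early, heat shock and unfolded protein response, mitochondrially encoded, nuclear oxidative phosphorylation, cytoplasmic ribosomal protein, SUMO and ubiquitin-like conjugation, and Wnt and R-spondin genes. Members were counted as called over all genes and after Benjamini-Hochberg adjustment over the list alone. Each list was tested with camera of limma (3.58.1) on log2 CPM (prior count 2) with the inter-gene correlation preset to 0.01, adjusted over the 35 lists. Camera compares a list with all other genes. The test was repeated with a correlation estimated from the data, under which 0 of the 35 lists passed, and with fry, which tests whether a list's genes move on balance in 1 direction. Called lists overlap in members, such as Tagln in the muscle and SMAD3 target lists.

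Genes were named by a rule fixed at the same time: Rnf111, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM, a proper symbol and non-overlapping groups, up to 4 members of smallest p from each list in the text, and 16 genes of ovarian function and TGF-beta signalling given whatever their result. Of called genes, 580 that rose and 899 that fell met these conditions. Genes outside this rule are marked where they appear.

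Alternatives fixed at the same time were 2 other scalings (DESeq2's size factors and upper quartile, both in edgeR), no filter beyond 1 count, a stricter filter (1 CPM in 3 libraries and 50 counts in all), DESeq2 (1.42.0), limma-voom, the replicate number as a block, 1 surrogate variable from sva (3.50.0), removal of mitochondrially encoded and hemoglobin genes, and each library left out in turn. A stricter fold, a looser false discovery rate and both other list tests were also run. List tests under DESeq2 used its Wald statistic, and those under limma-voom its weights. All 10 ways to part the 6 libraries into 3 and 3 were tested in the same way.

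The procedure was tested on simulated counts for the same 16841 genes with 3 libraries per group and 200 genes changed. Of genes changed 2-fold, 62% were called, and of genes changed 1.5-fold, 39%. In all 109 genes were called, 8 of them not changed, and 1 gene and 0 lists were called when nothing was changed. Simulated genes were drawn independently of each other, whereas the real lists had estimated correlations of up to 0.899 (interferon response). The simulation therefore cannot show how often lists of correlated genes are called falsely. The common biological coefficient of variation of the real libraries was 0.176. The labels give no litter, cage or sequencing batch, so none could be separated from genotype, and other files or samples of the study are not used here.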

Results

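Ovaries of mice aged 3 months and taken at estrus, the phase around ovulation, were profiled by bulk RNA sequencing. The libraries fell into 2 genotypes, wild type and Rnf111+/-, with 3 libraries each, and the labels name each library after its own mouse. Rnf111 encodes Arkadia, a ubiquitin ligase that marks inhibitors of TGF-beta family signalling (SMAD7, SKI and SnoN, the product of Skil) for degradation. The heterozygous mice were made by CRISPR-Cas9 editing to model loss of 1 copy of RNF111, which the study links to premature ovarian insufficiency, the early loss of ovarian function. Each library held between 38261449 and 39474515 counts, and 3 counts, the smallest number treated as detected, corresponded to 0.0747 to 0.0784 CPM, the usual unit of counts scaled to the total of the library. Of 35415 genes in the count table, 9529 had no count in any library and 16841 were expressed highly enough to be tested. The 10 most abundant genes took 4.64 to 4.92% of the counts of a library, and mitochondrially encoded genes took 2.36 to 2.54%.

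The targeted gene was examined first in every library. Rnf111 was at 53.87 ± 0.477 CPM in wild-type ovaries (mean ± SD, n = 3) and at 44.6 ± 0.395 CPM in heterozygous ovaries (n = 3), a log2 fold change of -0.27 ± 0.07 (SE). The wild-type libraries held 2060, 2063 and 2130 Rnf111 counts, and the heterozygous libraries held 1773, 1759 and 1712. The heterozygous level was thus 82.8% of the wild-type level, with an interval of 2 standard errors reaching from 75.4 to 90.9%. All 3 heterozygous libraries lay below all 3 wild-type libraries, and the fall passed edgeR's quasi-likelihood test (adjusted p = 0.04). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 can give. The call was lost in 5 of the 6 fits that left out 1 library, with adjusted p from 0.106 to 0.146. It held without wild-type replicate 3 (0.0421). The call was also lost with upper-quartile scaling (0.0602), without a filter on low counts (0.0762) and with the replicate number as a block (0.0653). The sources used here do not give the edited position or which of the edited lines was sequenced, so a gene-level count does not check the allele itself.

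Between the genotypes, 1623 genes passed edgeR's test at a false discovery rate of 0.05: 657 rose and 966 fell in heterozygous ovaries. Of these, 226 rose and 291 fell by at least 1 on the log2 scale. The values of the 2 genotypes did not overlap for 32% of tested genes, and the median log2 fold change of all tested genes was -0.008. Chance gives 10% non-overlap on average for 3 against 3. Genes vary together, so a single split can depart far from that average, and the excess was not tested. On the first principal component, which held 61.2% of the variance of the 500 most variable genes, wild-type libraries lay between -30 and -17.4 and heterozygous libraries between 23.7 and 26.3. On the second component (23.5%), wild-type replicate 3 lay at -33.6, away from the other wild-type libraries at 14.3 and 12.1. Its log2 CPM correlated across genes at 0.9735 and 0.9745 with the other wild-type libraries, against 0.9887 between those 2 and 0.9861 to 0.9885 among heterozygous libraries. Leaving out wild-type replicate 3 raised the number of changed genes to 2795, of which 1579 were shared with the fit of all libraries. The number was 865 without wild-type replicate 1, 826 without wild-type replicate 2, and 859, 530 and 557 without heterozygous replicates 1, 2 and 3.

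**Figure D1:**
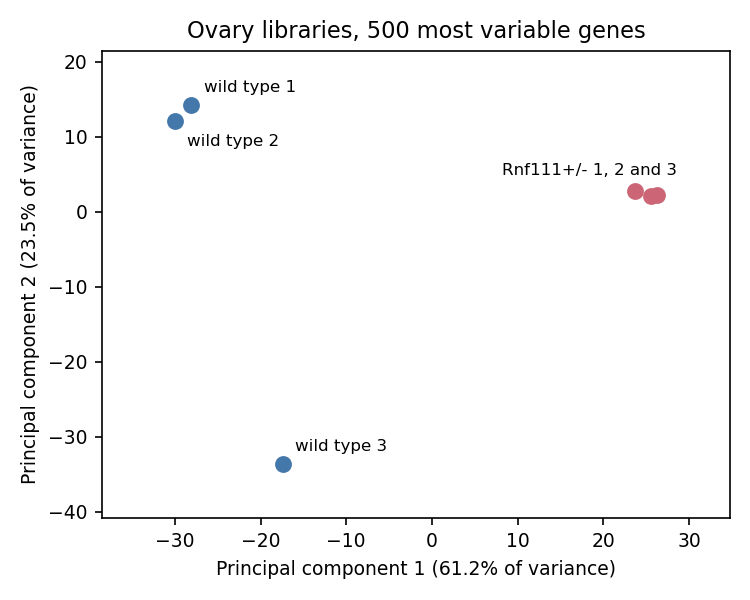
First and second principal components of log2 CPM for the 500 most variable genes, each point 1 ovary library (blue wild type, red Rnf111+/-, n = 3 each), with the percent of variance on each axis. The genotypes are apart on the first component, and wild-type replicate 3 is apart from the other wild-type libraries on the second.

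The largest rise among genes with a mean of at least 1 CPM was that of Cyp17a1, the theca enzyme that makes androgens, from 2.82 ± 1.53 to 197 ± 54.1 CPM (SD, n = 3 each). This was a 69.9-fold difference, or 6.13 ± 0.45 on the log2 scale (SE, adjusted p = 0.00173). Grem1, a secreted antagonist of bone morphogenetic proteins (BMPs) made by granulosa cells, rose 44.2-fold (log2 5.46 ± 0.41, adjusted p = 0.000589). Crhr1, a receptor for corticotropin-releasing hormone, rose 32.4-fold from 7 counts summed over the wild-type libraries to 242 over the heterozygous libraries (log2 ratio of the sums 5.09, counting interval 4.03 to 6.42). The other large rises were those of Lrrtm3 (13.5-fold), Rgs13 (13.1-fold), Mug1 (12.4-fold), Mylk4 (11.8-fold), Mug2 (10.7-fold), Meox2 (9.95-fold) and Comp (9.25-fold). Mug1 and Mug2 are close copies of each other, so how their reads were divided is uncertain. The steepest fall was that of Cyp11b1, which encodes steroid 11-beta-hydroxylase, with 624, 187 and 864 counts in wild-type libraries and 4, 0 and 0 in heterozygous libraries. The log2 ratio of its summed counts was -8.73 (counting interval -10.61 to -7.37), and the fitted value of -8.60 ± 1.03 depends on the prior count at such levels. Adcyap1, which encodes the neuropeptide PACAP that the ovulatory hormone surge induces in granulosa cells, fell from 9.45 ± 4.16 to 0.194 ± 0.149 CPM (log2 -5.57 ± 0.57, adjusted p = 0.00194). Apln, which encodes the vascular peptide apelin, fell from 107 ± 52.6 to 4.78 ± 1.86 CPM (log2 -4.48 ± 0.56). The remaining large falls were those of Pik3c2g (-6.09), Xpnpep2 (-5.20), Ptprn (-4.91), Cdh15 (-4.88), Cdk15 (-4.84), Timp4 (-4.73) and Pappa2 (-4.58), all as log2 fold changes. With single libraries left out, the calls of Mylk4, Meox2, Pik3c2g, Pappa2, Apln and Cdh15 were each lost in at least 1 fit, with adjusted p of up to 0.133 (Cdh15), and those of the other 14 genes held in all 6 fits. With all libraries, the call of Apln was lost with the replicate number as a block (adjusted p = 0.0587). That of Pik3c2g was lost with limma-voom (0.0734), and that of Cdh15 with limma-voom (0.136) and without a filter (0.108).

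**Figure D2:**
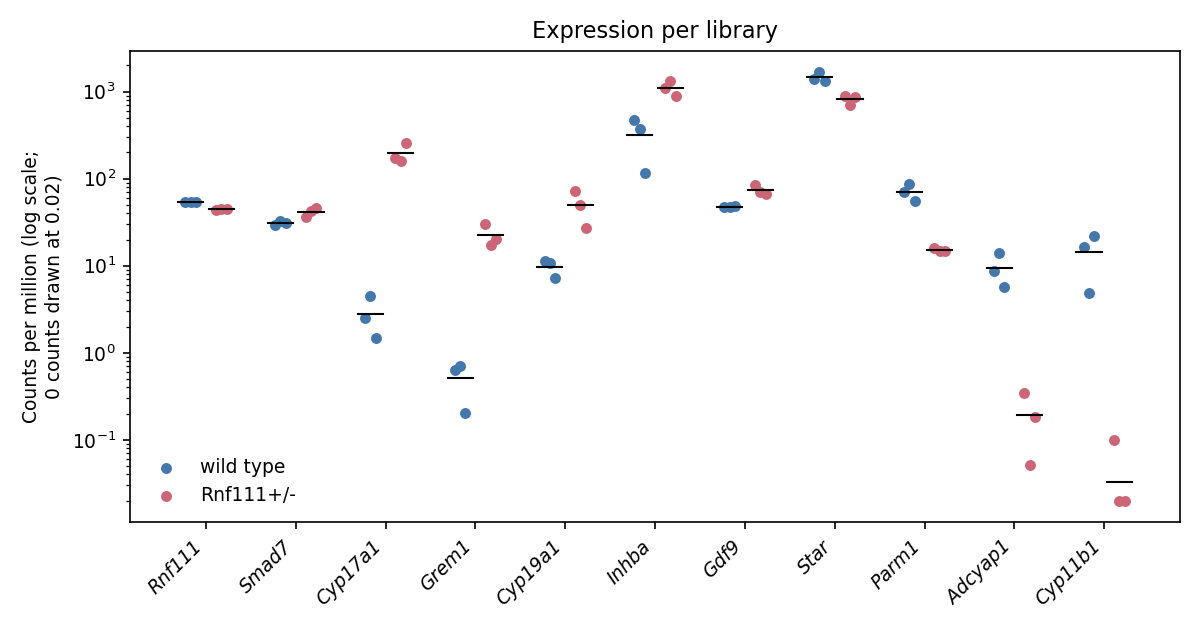
Expression of 11 genes in each ovary library as CPM on a log scale (blue wild type, red Rnf111+/-, each point 1 library, n = 3 per genotype, black bars the group means, 0 counts drawn at 0.02). Cyp17a1 rises 69.9-fold and Grem1 44.2-fold in Rnf111+/- ovaries, while Rnf111 itself is at 82.8% of the wild-type level.

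The somatic cells of the follicle were compared next. Among genes of granulosa cells of growing follicles, 5 of 30 rose (Grem1, Greb1, Bex4, Nr0b1 and Cyp19a1), 1 fell and 24 did not pass. The fall was that of Dcn, named after its value was seen. Adjusted over the list alone, 7 rose and 1 fell. Greb1, an estrogen-induced gene, rose from 395 ± 71 to 830 ± 9.64 CPM (log2 1.07 ± 0.12, adjusted p = 0.00179), and Nr0b1 and Bex4 rose by 1.27 ± 0.21 and 0.77 ± 0.11. Cyp19a1, the aromatase that converts androgens to estrogens, rose 5.09-fold from 9.80 ± 2.24 to 49.8 ± 22.4 CPM (log2 2.35 ± 0.39, adjusted p = 0.0188). Inhba, which encodes the activin and inhibin beta-A subunit (1.79 ± 0.54, adjusted p = 0.114), and the follicle-stimulating hormone receptor gene Fshr (1.08 ± 0.29, adjusted p = 0.068) did not pass, and neither did Fst (0.51, adjusted p = 0.463), Foxl2 (-0.24, adjusted p = 0.566) or Amh, at 377 ± 99.9 against 382 ± 149 CPM (0.02 ± 0.32, adjusted p = 0.981). With all libraries, Fshr and Inhba passed with DESeq2 (adjusted p = 0.000359 and 0.00442), limma-voom (0.0316 and 0.0334) and 1 surrogate variable (0.000263 and 3.63e-05). The granulosa list was called as higher by the camera test (median log2 0.24, adjusted p = 0.00364), and had an adjusted p = 0.753 with an estimated correlation. Granulosa genes were also lower in wild-type replicate 3 than in the other wild-type libraries, with a median log2 ratio of -0.62, and without that library 9 rose, and Fshr (0.81, adjusted p = 0.00102) and Inhba (1.40, adjusted p = 0.0146) passed. Without heterozygous replicate 2, 3 granulosa genes rose. The call of Cyp19a1 was lost in 4 of the 6 fits that left out 1 library (adjusted p up to 0.0725). With all libraries it was also lost without a filter on low counts (adjusted p = 0.0698).

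Theca and steroidogenic interstitial genes had 1 rise (Cyp17a1) and 4 falls among 21, and adjusted over the list alone 3 rises and 4 falls. Mgarp, a mitochondrial protein of steroidogenic cells, fell from 1084 ± 91.9 to 306 ± 12.3 CPM (log2 -1.83 ± 0.08, adjusted p = 6.89e-05). Star, which brings cholesterol into mitochondria, fell from 1465 ± 181 to 819 ± 98.9 CPM (-0.84 ± 0.12, adjusted p = 0.00467), and Srd5a1 fell by 0.73 on the log2 scale. The fourth fall was that of Hsd3b1 (-0.53), named after its value was seen. The list as a whole was not called (median log2 0.04, mean 0.20, adjusted p = 0.969), and the camera test put it higher where fry put it lower. Of genes of ovulation and cumulus expansion, 2 of 26 rose and 6 fell, and adjusted over the list alone 2 rose and 7 fell (median log2 -0.27, adjusted p = 0.112). Runx1, a transcription factor induced before ovulation, fell from 200 ± 13.4 to 66.1 ± 6.07 CPM (-1.60 ± 0.09, adjusted p = 0.00015), and the sphingosine kinase gene Sphk1 fell by 1.76. Nrip1 and Ctsl rose by 0.72 ± 0.08 and 0.55 ± 0.07. The luteinizing hormone receptor gene Lhcgr (-0.74 ± 0.56, adjusted p = 0.48) and the progesterone receptor gene Pgr (0.17 ± 0.34, adjusted p = 0.809) did not pass. With single libraries left out, the falls in the ovulation list numbered 6 without wild-type replicates 2 and 3, 3 without wild-type replicate 1, 2 without heterozygous replicates 1 and 2, and 1 without heterozygous replicate 3. The ovulation list itself passed without wild-type replicate 2 (adjusted p = 0.0233), on DESeq2's statistics (adjusted p = 0.0179) and without a filter on low counts (adjusted p = 0.0294).

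Genes of the corpus luteum, the gland that forms from the ovulated follicle, had 6 falls and no rise among 23, and adjusted over the list alone 8 falls and 2 rises. Parm1 fell from 70.5 ± 15.9 to 15.2 ± 0.711 CPM (log2 -2.22 ± 0.16, adjusted p = 0.000323). Fdxr, the reductase that feeds electrons to mitochondrial steroid hydroxylases, fell from 514 ± 15.4 to 268 ± 17.9 CPM (-0.94 ± 0.07, adjusted p = 0.000341). The cell cycle inhibitor gene Cdkn1b fell by 1.09 on the log2 scale. Of 3 luteal genes chosen after their values were seen, Akr1c18, which inactivates progesterone, was at 276 ± 346 against 2420 ± 380 CPM (3.13 ± 1.06, adjusted p = 0.153), Sfrp4 at 445 ± 388 against 2616 ± 741 CPM (2.56 ± 0.71, adjusted p = 0.0972) and Ptgfr at 202 ± 218 against 699 ± 151 CPM (1.79 ± 0.84, adjusted p = 0.268). In wild-type replicate 3 these 3 genes were at 676, 890 and 454 CPM, above the other wild-type libraries. Without that library all 3 passed, Akr1c18 at 4.99 ± 0.21 (adjusted p = 6.9e-05), Sfrp4 at 3.56 ± 0.38 (adjusted p = 0.0113) and Ptgfr at 3.2 ± 0.21 (adjusted p = 0.000482). The list's median (-0.43) and mean (0.05) differed in sign, and the camera test, which put it lower, did not pass (adjusted p = 0.112). Without wild-type replicate 3, 9 luteal genes fell and 4 rose, without heterozygous replicate 2, 3 fell, and without heterozygous replicate 3 the list passed (adjusted p = 0.0386). It also passed with camera run on DESeq2's statistics (adjusted p = 0.000283) and with upper-quartile scaling (adjusted p = 0.0493).

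Of cholesterol synthesis genes, 6 of 24 fell and none rose, and 8 fell when adjusted over the list alone. Hmgcs1, which makes the substrate of the rate-limiting step, fell from 674 ± 164 to 255 ± 7.06 CPM (log2 -1.40 ± 0.16, adjusted p = 0.00327), and Mvk and Msmo1 fell by 0.90 and 0.63. With all libraries, the call of Mvk was lost without a filter on low counts (adjusted p = 0.0698). The list was called as lower (median log2 -0.64, adjusted p = 3.15e-05), with adjusted p = 0.753 with an estimated correlation. Nuclear genes of oxidative phosphorylation had 15 falls among 39 and no rise, and 23 falls adjusted over the list alone, with 38 of the 39 below 0. The falls were small, such as those of Ndufa4 (-0.49 ± 0.07, adjusted p = 0.00447), Ndufa5 (-0.45 ± 0.08), Cox6b1 (-0.44 ± 0.08) and Ndufb7 (-0.43 ± 0.07), and the median was -0.22. The list was called as lower by camera (adjusted p = 2.19e-08) and by fry (adjusted p = 0.0155), and had adjusted p = 0.623 with an estimated correlation. Mitochondrially encoded genes had no call among 13 by edgeR or DESeq2, and 0 at an unadjusted p under 0.05 (median log2 0.01, mean -0.04, adjusted p = 0.831). Counts of falls were 11 for cholesterol synthesis and 18 for oxidative phosphorylation without wild-type replicate 3. They were 4 and 4 without wild-type replicate 1, 4 and 7 without wild-type replicate 2, and 3 and 3, 2 and 1, and 1 and 4 without heterozygous replicates 1, 2 and 3, while both lists stayed called in all 6 fits. Without wild-type replicate 2, 2 cholesterol synthesis genes rose.

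Of oocyte genes, 18 of 44 rose and none fell, and adjusted over the list alone 38 rose and none fell. Gdf9, an oocyte growth factor of the TGF-beta family, rose from 47.7 ± 1.11 to 73.9 ± 9.56 CPM (log2 0.63 ± 0.10, adjusted p = 0.00707). Zp1, a protein of the egg coat, rose by 0.81 ± 0.14, and Zar1 and Tcl1, which act in the early embryo, by 0.78 ± 0.14 and 0.74 ± 0.14. Bmp15, the partner of Gdf9, rose from 14.8 ± 1.81 to 21.4 ± 1.90 CPM (0.54 ± 0.13, adjusted p = 0.0356). The oocyte list was called as higher (median log2 0.67, adjusted p = 1.33e-17), with 42 of 44 members above 0, and had adjusted p = 0.623 with an estimated correlation. Of genes linked to premature ovarian insufficiency, 3 of 38 rose (Gdf9, Bmp15 and Nobox, an oocyte transcription factor, at 0.81 ± 0.18), none fell, and the count was the same adjusted over the list alone (median log2 0.03, adjusted p = 0.24). Bmpr1b, a BMP receptor gene of that list, was at 1.27 ± 0.31 (adjusted p = 0.0602). It passed with a stricter filter (adjusted p = 0.0441), DESeq2 (0.00531), limma-voom (0.0231) and 1 surrogate variable (8.24e-05), and without wild-type replicate 3 (0.99 ± 0.10, adjusted p = 0.000162). Oocyte genes that rose numbered 13, 4 and 22 without wild-type replicates 1, 2 and 3, and 5, 2 and 10 without heterozygous replicates 1, 2 and 3. The list stayed called in all 6 of these fits, and the calls of Gdf9 and Zar1 held in each, while those of Zp1, Tcl1, Bmp15 and Nobox were lost in at least 1 (adjusted p up to 0.144 for Bmp15).

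The pathway that Arkadia acts on was examined through 5 lists. Of SMAD feedback genes and Arkadia substrates, 3 of 13 rose and none fell, and the count was the same adjusted over the list alone. They were Nedd4l, a ubiquitin ligase for activated SMADs (log2 0.75 ± 0.13, adjusted p = 0.0107), the corepressor gene Tgif1 (0.47 ± 0.10, adjusted p = 0.0256) and Smad7, at 30.9 ± 1.87 against 41.9 ± 5.19 CPM (0.44 ± 0.11, adjusted p = 0.0398). The Arkadia substrate genes Skil (0.34 ± 0.14, adjusted p = 0.171), Ski (0.14 ± 0.06, adjusted p = 0.201) and Axin1 (0.22 ± 0.08, adjusted p = 0.112) did not pass. These are RNA levels, and the amount of the proteins that Arkadia marks for degradation was not measured here. The list was called as higher (median log2 0.22, adjusted p = 0.0131), with adjusted p = 0.623 with an estimated correlation. Without wild-type replicate 3 it had 5 rises, and Skil passed (0.53, adjusted p = 0.00053). The list had 1 rise without wild-type replicate 2 or heterozygous replicate 2, and 0 without heterozygous replicate 3. The call of Smad7 was lost in 4 of the 6 fits without 1 library. With all libraries it was also lost with limma-voom (adjusted p = 0.0502).

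Among TGF-beta, BMP and activin ligands and their antagonists, 5 of 27 rose and 2 fell, and adjusted over the list alone 13 rose and 4 fell. Beside Grem1, Gdf9 and Bmp15, the BMP antagonist gene Chrdl1 rose by 1.32 ± 0.20 (adjusted p = 0.00634), Gdf10 fell by 0.84, and, named after their values were seen, Bmp3 rose by 1.65 and the antagonist gene Chrd fell by 1.58. The list was called as higher (median log2 0.39, adjusted p = 0.0155), with adjusted p = 0.623 with an estimated correlation. Without wild-type replicate 3 that call was lost (adjusted p = 0.0626), although 10 members rose and 4 fell. There were 4 rises and 1 fall without wild-type replicate 1, 3 and 0 without wild-type replicate 2, and 5 and 1, 3 and 1, and 3 and 0 without heterozygous replicates 1, 2 and 3. Of receptors and SMADs, 1 of 20 rose (Smad3, 0.40 ± 0.08) and 2 fell, the BMP and activin receptor gene Acvr1 (-0.67 ± 0.12, adjusted p = 0.0152) and Acvrl1 (-0.38 ± 0.10, adjusted p = 0.0499). Adjusted over the list alone 5 rose and 2 fell, and the list was not called (median log2 0.04, adjusted p = 0.626). The call of Acvrl1 was lost in 5 of the 6 fits without 1 library (adjusted p up to 0.195), and those of Acvr1 and Smad3 in 3 and 2. With all libraries the call of Acvrl1 was also lost with DESeq2's size factors (adjusted p = 0.0543), upper-quartile scaling (0.0649), no filter (0.056), a stricter filter (0.053), the replicate block (0.0588) and without mitochondrially encoded and hemoglobin genes (0.0534).

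Transcriptional targets of the pathway followed. Of TGF-beta and SMAD3 targets, 3 of 22 rose and 5 fell, and adjusted over the list alone 3 rose and 6 fell, with a median of -0.02, a mean of 0.01 and no call (adjusted p = 0.831). The contractile gene Tagln fell from 409 ± 70.8 to 187 ± 25.4 CPM (log2 -1.13 ± 0.14, adjusted p = 0.00447), and the matrix genes Col1a1, Tgfbi and Fn1 fell by 0.68, 0.65 and 0.49. The rises, of which Ccn2 and Thbs1 were named after their values were seen, were those of Ccn2 (1.70 ± 0.31, adjusted p = 0.027), Thbs1 (0.62) and Smad7. Of BMP and SMAD1/5 targets, 1 of 15 rose (Smad7) and 2 fell, and adjusted over the list alone 2 rose and 2 fell, with a median of 0.08 and no call (adjusted p = 0.969); fry put this list lower. Id2 fell from 182 ± 18 to 65.1 ± 5.98 CPM (-1.49 ± 0.10, adjusted p = 0.00015) and Runx2 by 1.34, while Id1 was at 27 ± 4.90 against 29.4 ± 6.11 CPM (0.12 ± 0.18, adjusted p = 0.735) and Msx2 at 2.03 ± 0.63 (adjusted p = 0.0808). The call of Runx2 was lost in 4 of the 6 fits without 1 library (adjusted p up to 0.107), and those of Col1a1 and Tgfbi in 2 each. With all libraries the call of Runx2 was also lost without a filter (adjusted p = 0.0933) and with the replicate block (0.0709). Rises and falls of TGF-beta and SMAD3 targets numbered 0 and 4, 3 and 4, and 5 and 6 without wild-type replicates 1, 2 and 3, and 2 and 3, 1 and 2, and 0 and 3 without heterozygous replicates 1, 2 and 3. Those of BMP and SMAD1/5 targets were at most 2 in each of these fits.

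Stromal and vascular genes were compared next. Of stromal fibroblast and matrix genes, 11 of 29 fell and none rose, and adjusted over the list alone 17 fell and 1 rose. The collagen gene Col3a1 fell from 1348 ± 230 to 664 ± 75.8 CPM (log2 -1.02 ± 0.13, adjusted p = 0.00395), Lum fell by 0.92, and Sparc and Col5a2 both fell by 0.88. Of smooth muscle and pericyte genes, 6 of 22 fell and none rose, and adjusted over the list alone 7 fell, among them Tagln, Lmod1 (-0.94 ± 0.17), Mcam (-0.80 ± 0.08) and Smtn (-0.47 ± 0.07). Of endothelial genes, 7 of 22 fell and none rose, and adjusted over the list alone 8 fell, with smaller changes for the vascular growth factor receptor genes Flt1 (-0.57 ± 0.12) and Kdr (-0.39 ± 0.08) and the junction genes Cdh5 (-0.51 ± 0.10) and Cldn5 (-0.40 ± 0.08). The camera test called the stromal (median -0.49, adjusted p = 7.15e-06), muscle (-0.45, adjusted p = 0.000217) and endothelial (-0.31, adjusted p = 0.000256) lists as lower. These 3 lists had adjusted p = 0.623, 0.753 and 0.753 with an estimated correlation, and fry called none of them (adjusted p = 0.059, 0.0874 and 0.171). With single libraries left out, falls numbered 5 (without heterozygous replicate 1 or 2) to 18 (without wild-type replicate 3) in the stromal list, 3 (without heterozygous replicate 2) to 6 in the muscle list and 0 (without heterozygous replicate 2) to 6 in the endothelial list, and the 3 lists stayed called.

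Ovarian surface epithelium genes had 5 falls and 1 rise among 17, and adjusted over the list alone 7 falls and 1 rise. Lrrn4, Krt19 and the mesothelial marker gene Msln fell by 0.86, 0.60 and 0.45 on the log2 scale, and the stem cell marker Lgr5 rose from 46.6 ± 1.19 to 78.1 ± 5.46 CPM (0.74 ± 0.08, adjusted p = 0.00114). Of Wnt and R-spondin genes, 7 of 26 fell and 1 rose (Lgr5, which is in both lists), and adjusted over the list alone 7 fell and 2 rose. Wnt6 fell from 90.9 ± 12.9 to 32.8 ± 1.91 CPM (-1.47 ± 0.11, adjusted p = 0.000285), Wnt5a by 0.94, and Axin2, a target of canonical Wnt signalling, by 0.82. Neither list was called in the main fit (surface epithelium median -0.32, adjusted p = 0.0666; Wnt median -0.16, adjusted p = 0.162). With single libraries left out, surface epithelium genes that fell numbered 2, 2 and 5 without wild-type replicates 1, 2 and 3 and 2, 1 and 1 without heterozygous replicates 1, 2 and 3, and Wnt and R-spondin genes that fell 6, 4 and 8, and 3, 4 and 2. The call of Msln was lost in 5 of these fits (adjusted p up to 0.131) and, with all libraries, with the replicate block (0.0564). The surface epithelium list passed in 4 of the 6 fits without 1 library, with adjusted p from 0.0113 (without wild-type replicate 1) to 0.38 (without wild-type replicate 3). With all libraries it also passed with upper-quartile scaling (adjusted p = 0.046), without a filter (0.0294), on DESeq2's statistics (0.0471), with limma-voom (0.0404) and with the replicate block (0.0447), and the Wnt list passed on DESeq2's statistics (0.0145).

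Immune and oviduct genes set wild-type replicate 3 apart. Against the other wild-type libraries, its median log2 ratio was 1.42 for interferon response genes, 1.25 for oviduct epithelium genes, 1.05 for adipocyte genes, 1.03 for macrophage and myeloid genes and 0.99 for lymphocyte genes. Ovgp1, an abundant secreted oviduct protein, had 71, 242 and 5730 counts in wild-type replicates 1, 2 and 3 and 104, 315 and 187 in the heterozygous libraries, and the cilia gene Foxj1 had 2, 20 and 535 against 21, 66 and 20. Both genes were named after their values were seen. Between genotypes, 3 of 28 interferon response genes fell and none rose, also when adjusted over the list alone: Gbp2 (log2 -1.04 ± 0.18, adjusted p = 0.0172), Ifit3b (3.99-fold lower) and Ifi27l2a (-1.71 ± 0.36), while Ifit3 did not pass (-1.66 ± 0.45, adjusted p = 0.0684). Ifit3 passed with DESeq2 (adjusted p = 0.000173), with 1 surrogate variable (0.000617), and without wild-type replicate 1 (0.0206) or 3 (0.0141). With all libraries, the call of Ifit3b was lost with limma-voom (adjusted p = 0.0526) and that of Ifi27l2a without a filter on low counts (0.124). The interferon list was called as lower (median -1.17, adjusted p = 3.9e-05), with adjusted p = 0.753 with an estimated correlation, and without wild-type replicate 3 its median was -0.27 with 7 falls (adjusted p = 0.00232). Without heterozygous replicate 1 or 2, 0 interferon genes fell, and with 1 surrogate variable as a covariate 22 of 28 did (median -0.819, adjusted p = 7.78e-13). Of oviduct genes, only Epcam fell among 20 (-0.54 ± 0.08, adjusted p = 0.00527), also when adjusted over the list alone, and Dnah5 (-4.45 ± 1.86), Ccdc153 (-3.31 ± 1.51) and Cdhr4 (-2.67 ± 1.12) did not pass. Cdhr4 passed with DESeq2 (adjusted p = 0.0147). With 1 surrogate variable, Cdhr4 (-1.56, adjusted p = 0.00922) and Dnah5 (-2.33, adjusted p = 0.0035) passed. The oviduct list's median was -0.40 (adjusted p = 0.269) and turned to 0.17 without wild-type replicate 3, while without wild-type replicate 1 the list was called as lower (median -0.539, adjusted p = 0.0113). Macrophage and myeloid genes had no call among 22 (median -0.05, camera direction higher, adjusted p = 0.831), but 6 rises and a called list without wild-type replicate 3 (median 0.40, adjusted p = 0.0047), and lymphocyte genes had none among 17 (median 0.08, adjusted p = 0.831). At an unadjusted p under 0.05, 2 macrophage and 1 lymphocyte genes passed edgeR's test, and DESeq2 called 1 gene of each list.

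**Figure D3:**
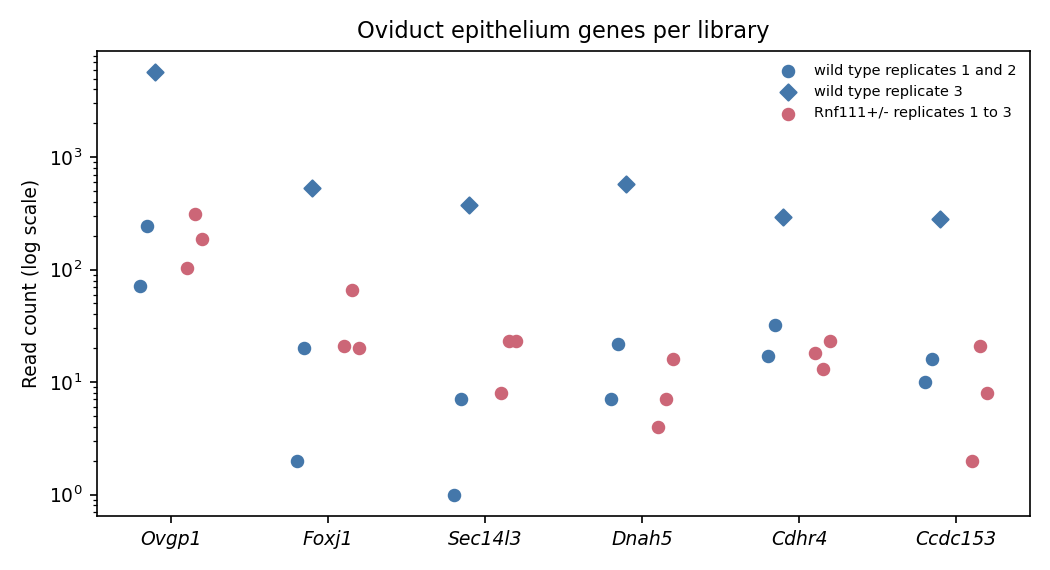
Read counts of 6 oviduct epithelium genes in each library on a log scale (blue wild type, red Rnf111+/-, each point 1 library, wild-type replicate 3 as diamonds). Wild-type replicate 3 holds 5730 Ovgp1 counts, against 71 to 315 in the other 5 libraries. Of the 20 oviduct genes tested, these 6 had the largest log2 ratios of that library to the other wild-type libraries (3.53 to 6.17).

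The remaining lists had at most 3 calls each over all genes, and none was called by camera. Their members in the text were named after their values were seen. Inflammatory cytokine and chemokine genes had 1 fall among 23, Cxcl12 (log2 -1.47 ± 0.14), also when adjusted over the list alone (list median -0.30, adjusted p = 0.24). Adipocyte genes had 1 rise, Pparg (0.70), and 1 fall, Lipe (-0.36), among 13, and 2 rises and 1 fall adjusted over the list alone (median 0.06, adjusted p = 0.829). Erythrocyte genes had 1 rise among 8, Bpgm (0.44), in both counts (median 0.50, adjusted p = 0.248). Immediate early genes had 1 rise, Fos (1.27 ± 0.18), and 2 falls, Fosl1 (-2.31) and Btg2 (-0.82), among 22, in both counts (median 0.08, adjusted p = 0.731). Senescence-associated genes had 2 falls among 19, with Igfbp4 at -0.69, and 5 falls and 1 rise adjusted over the list alone, with a median of 0.08, a mean of -0.04 and no call (adjusted p = 0.819). Genes of primordial follicle activation and PI3K-FOXO3 signalling had 2 rises, Nobox and Kit (0.69), and 1 fall, Cdkn1b, among 20, and 3 rises and 1 fall adjusted over the list alone (median 0.04, adjusted p = 0.512). Heat shock and unfolded protein response genes had 1 rise, Pdia4 (0.90), and 2 falls, Sdf2l1 (-0.54) and Hspd1 (-0.45), among 26, and 2 rises and 2 falls adjusted over the list alone (median -0.16, adjusted p = 0.205). Genes of p53 and apoptosis had 1 fall among 26, Ccng1 (-0.40), and 0 adjusted over the list alone, with a median of -0.03, a mean of 0.02 and no call (adjusted p = 0.969). No member passed edgeR's test, over all genes or adjusted over the list alone, among 34 cell cycle genes (median -0.05, adjusted p = 0.64), 33 DNA repair and meiotic recombination genes (0.06, adjusted p = 0.573), 49 cytoplasmic ribosomal protein genes (-0.02, adjusted p = 0.828) and 23 SUMO and ubiquitin-like conjugation genes (-0.02, adjusted p = 0.831). At an unadjusted p under 0.05, 2, 5, 3 and 1 genes of these 4 lists passed, and DESeq2 called 0, 1, 1 and 0.

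**Figure D4:**
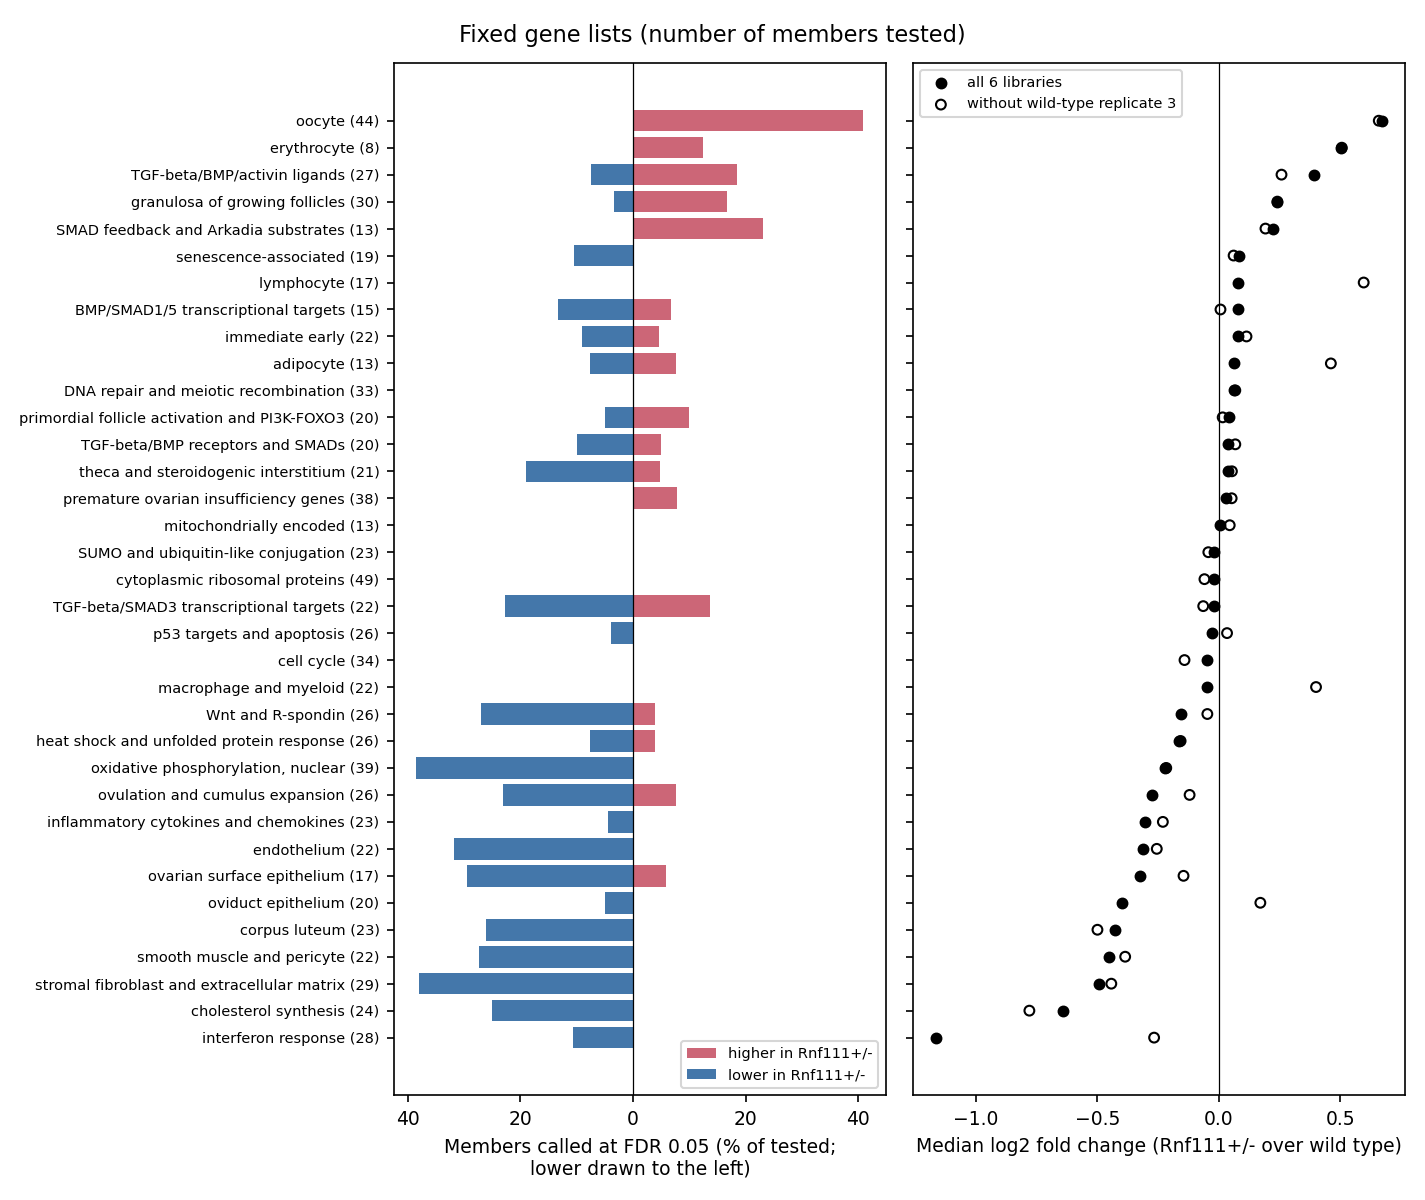
Left, percent of tested members of each of the 35 gene lists called at an adjusted p of 0.05 as higher (red, right of 0) or lower (blue, left of 0) in Rnf111+/- ovaries, with the number tested in parentheses. Right, each list's median log2 fold change with all 6 libraries (filled) and without wild-type replicate 3 (open), where the interferon list moves from -1.17 to -0.27 and the oocyte list from 0.67 to 0.66.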

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

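All alternatives here were set before their results were seen. The fall of Rnf111 kept its direction under every setting, but its call was lost with upper-quartile scaling (log2 -0.24, adjusted p = 0.0602), without a filter on low counts (-0.27, 0.0762), and in 5 of 6 fits without 1 library (-0.27 to -0.26, adjusted p up to 0.146, with fewer libraries). The 1623 changed genes became 1621 with DESeq2's size factors in edgeR, 1628 with upper-quartile scaling, 1782 without a filter, 1643 with a stricter filter, 1593 with limma-voom and 1626 without mitochondrially encoded and hemoglobin genes. They became 2615 with DESeq2's test, which called all 1623 again, and 3431 with 1 surrogate variable, which called 1616 of them; the cause was not tested. Without single libraries they ran from 530 (without heterozygous replicate 2) to 2795 (without wild-type replicate 3). A minimum log2 fold change of 1 left 517, and a false discovery rate of 0.1 gave 2632. The share of calls that fell was 59.5%, and 51.4% with upper-quartile scaling.

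The replicate numbers are shared by the genotypes, but the labels do not say whether they pair the mice. Same-numbered libraries deviated together by r = 0.012, 0.006 and 0.1 across genes, which neither shows nor excludes pairing. With the replicate number as a block, 1626 genes were called, 1348 of them shared, and Rnf111 was at -0.27 (adjusted p = 0.0653). Of the 6 libraries, only the 2 numbered 3 correlated best with their own number.

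The 10 called lists numbered 10 to 14 under the other scalings, filters, gene tests and left-out libraries, and 9 of them were called in all 6 fits without 1 library. With an estimated correlation 0 lists passed, and 2 had an unadjusted p under 0.05, and fry called 1, oxidative phosphorylation. These tests allow for the correlation of genes within a list.

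For the 101 other named genes, 1351 of 1508 comparisons with an alternative kept direction and side of the threshold, 128 lost the call, 23 gained one and 6 changed sign, all in genes that were not called. Amh, at 0.02, was at -0.01 with limma-voom and with the block, and from -0.35 (without heterozygous replicate 1) to 0.19 without single libraries, with -0.17 without wild-type replicate 3. Id1 (0.12) ranged from -0.01 to 0.28 and Pgr (0.17) from -0.21 to 0.37, both lowest without heterozygous replicate 3; the cause was not tested. Of 85 named genes called, 41 stayed called in all 6 fits without 1 library. Depth limits little at 38261449 counts or more, but genes near the floor, such as Cyp11b1 and Crhr1, have wide counting intervals.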

Other observations

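Of the tests below, those of other splits of the genes and lists called, and of the oocyte list's common shift, were set before their results were seen, the latter once the list's rise was known, and those of genes moved by the hormone surge, of the granulosa list's common shift, of single libraries, of scaling and of wild-type replicate 3 were chosen only after. Genes in the next 2 paragraphs were also chosen after their values were seen.

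Several single genes outside the fixed lists rose in heterozygous ovaries; they were not tested as groups. Serpina3c rose 5.86-fold, Serpina5 5.06-fold, from 27.9 ± 9.47 to 141 ± 35.2 CPM (SD, n = 3), Itih2 3.21-fold, and Clu 2.14-fold, from 1279 ± 170 to 2735 ± 426 CPM. The GABA receptor subunit gene Gabrb2 rose 8.27-fold (2.26 ± 1.26 to 18.7 ± 3.24 CPM) and the calcium channel gene Cacna1d 2.46-fold. Ass1, an enzyme of arginine synthesis, rose 5.96-fold (5.37 ± 0.319 to 32 ± 10.2 CPM). All passed edgeR's test, with adjusted p from 0.000672 (Ass1) to 0.0102 (Serpina3c).

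Among genes that fell, Tinagl1, a matrix protein, had the smallest p of all genes, with 155 ± 11.5 against 28.3 ± 1.91 CPM (log2 -2.46 ± 0.09, adjusted p = 1.5e-05). Further log2 fold changes of genes that fell were -2.53 for Alpl, alkaline phosphatase, -2.72 for the oxytocin receptor gene Oxtr, -2.78 for the chemokine receptor gene Cxcr4 and -1.47 for its ligand gene Cxcl12. They were -2.07 and -3.08 for Prss35 and Adamts1, proteases of the ovulating follicle, -1.49 for Hdc, which makes histamine, and -1.51 and -1.28 for the metallothionein genes Mt2 and Mt1, whose sequences are much alike.

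Over the 9 other splits of the libraries, the highest number of genes called was 0, against 1623 for the genotypes. Each of those 9 splits mixes the genotypes within its groups, so a difference between the genotypes widens the spread there. The 0 is therefore not the level that chance would give. With 3 libraries per genotype only 10 splits exist, too few to give a share under 0.05, and 1 of the 10, the real one, gave as many genes. For the lists, 6 of the 10 splits gave at least the 10 called lists of the real one, and the highest other split gave 17.

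The first pattern is in single genes. Of the granulosa, theca, ovulation and corpus luteum lists together, 23 members were called, 8 as higher (such as Cyp17a1, Grem1, Cyp19a1, Nrip1 and Ctsl) and 15 as lower (such as Runx1, Star and Parm1), and of the 4 lists the granulosa list was called as a whole in the main fit (adjusted p = 0.00364, and 0.753 with an estimated correlation), while the ovulation and corpus luteum lists passed under some other settings. A larger share of granulosa cells of unchanged make-up is argued against as the only cause, since 9 of 30 granulosa genes departed from the list's common shift. The list does not part granulosa cells by follicle stage. A larger share of those of some stages could also shift its genes unequally, and was not tested. Wild-type replicate 3 as the driver was tested on these 23 genes only. They were picked as called with that library included, and the groups of all 1623 changed genes do not overlap, so large losses were unlikely beforehand. The test shows that these changes do not rest on that library, and cannot decide for members that were not called. Without it the 23 genes kept at least 76% of their log2 fold change, and 22 stayed called. Even less 1 SE, 0 fell under 50%. The call of Cyp19a1 was lost (2.35 ± 0.39 before, 2.18 ± 0.51 after, adjusted p = 0.0725), with fewer libraries and a larger error. This bound was set after the values were seen and replaced others: that each of 6 picked genes stay called, which 5 did, that these 6 keep at least 80%, which they did at 93% or more, and that all 23 keep 80%, which 22 did, with Adamts1 at 76%. A candidate explanation is that the ovaries of the 2 genotypes stood at different times around the ovulatory hormone surge: 12 genes that the surge lowers had a median log2 fold change of 0.28 and 12 that it raises one of -0.07, a difference of 0.35 at the percentile 100, as rounded, of 10000 random pairs of lists matched on expression. Of these 24 genes, 19 are also in fixed lists whose results had been seen, so the test is not independent of the pattern. By that percentile alone, the first form of the test, the timing would have been supported, and the comparison with other splits of the libraries was added after. They gave differences of up to 0.77 in size, so the difference of the medians does not decide. None of the 24 genes was called, where 1623 of all 16841 tested genes were. No single gene of the 24 thus carries the timing at that threshold. The 23 called members, none of which is among the 24, were not part of the test. Without wild-type replicate 3, of the raised genes Sfrp4 (3.56), Ptgfr (3.2), Plat (0.53) and Tnfaip6 (1.47) passed edgeR's test as higher. Prlr (-0.66) and Vegfa (-0.5) were lower and did not pass. These genes were picked after their values were seen. The timing stays open, as does an effect of genotype on follicle maturation, which the design cannot part from cycle timing.

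The second pattern is the rise of oocyte genes. Scaling of the libraries is argued against for the rise relative to other genes. A scaling factor moves all genes of a library alike, whereas 42 of 44 oocyte genes were above 0 and the median of all genes was -0.008. Scaling was not decided for the absolute amount of oocyte RNA. The list's median log2 fold change was at least 0.67 under 4 scalings, but these moved the median of all genes only from -0.008 to 0.023. A larger share of oocyte RNA in heterozygous libraries, from more or larger oocytes relative to the other tissue, may account for it. Of 40 oocyte genes of at least 1 CPM, 0 departed from the list's median shift, in a test that found 9 departures among granulosa genes. Those 9 were of 0.659 (Bex4) or more in size, near the oocyte list's whole median of 0.67. Smaller unequal shifts could thus be missed, and Ddx4 at -0.499 and Tle6 at -0.366 were not flagged. Whether more oocytes, less surrounding tissue or the part of the ovary taken, which the labels do not give, lies behind such a share was not tested.

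The third pattern is the distance of wild-type replicate 3 from the other wild-type libraries. Oviduct cells in that library could explain its higher oviduct genes. The list's median log2 ratio to the other wild-type libraries was 1.25, with Ovgp1 at 5730 counts against 71 and 242. This was above that of every other cell type list, of which the adipocyte list came next at 1.05. Between wild-type replicates 2 and 1 the median log2 ratio was 0.41 for oviduct genes and 0.43 for adipocyte genes. Not all of the 20 oviduct genes tested were higher to that extent: the log2 ratio was -0.07 for Epcam, also expressed in the ovary, 0.04 for Elf3, 0.19 for Sox17, 0.39 for Wfdc2 and 0.48 for Cfap126. All of these but Epcam were named after their values were seen. Dilution by such cells is argued against for its lower granulosa genes (median log2 ratio -0.62), since dilution lowers all ovarian genes alike and oocyte genes were at -0.08 (interval over genes -0.18 to 0) and theca genes at -0.18 (-0.34 to 0.28), against -0.89 to -0.36 for granulosa genes. Corpus luteum genes (-0.26, -0.47 to 0.3) and cholesterol synthesis genes (-0.36, -0.67 to -0.16) overlap the granulosa interval and do not decide. Interferon (1.42), adipocyte (1.05), macrophage (1.03) and lymphocyte (0.99) genes were higher in it too. No biological explanation was tested for these, since the labels give this mouse nothing that sets it apart.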
